A study of Mus musculus with 2 samples.

How the data were processed

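The series holds 2 libraries of one group: nuclei from mouse cortex, stained for NeuN (the neuronal nuclear protein encoded by Rbfox3) and collected by flow sorting. The mice carried APOBEC1-YTH, a fusion of the cytidine deaminase APOBEC1 to the m6A-binding YTH domain. The fusion binds RNA at N6-methyladenosine (m6A) and converts cytidines beside the modified adenosine to uridines, which appear in sequenced cDNA as C-to-T changes, so that C-to-U sites serve as a readout of m6A. Per the labels' protocols, mice were 10 weeks old at the first dose of tamoxifen (20 mg/kg each 24 hours for 5 days), tissue was taken 7 days after the last dose, and nuclei were fixed in 50% ethanol before staining. The labels do not say whether each library came from 1 animal. One label field names polyA RNA while the protocol names a stranded total RNA kit for low input, so the RNA fraction that was sequenced is uncertain.

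The authors deposited 1 table for both libraries: a list of single-base sites with chromosome, position, strand, gene name and an editing fraction per site. Per the series description the sites were called with Bullseye, a pipeline that finds C-to-U conversions, and per the submitters' processing notes reads were aligned with STAR 2.7.5 and the build was mm10. The Bullseye settings, the control it was run against, the coverage minimum and the way the 2 libraries were combined are not given in the sources used here. The values start at 1.00% and 500 of them lie from there to under 1.1%, so the list stops sharply at that level. Of the values, 125 carry 5 decimals and each of those 125 ends in 5, while the rest carry 4 or fewer. No columns of per-library values and 0 columns of coverage are in the table, so the depth is unknown, no counting interval can be given for an editing level, and no spread between the 2 libraries can be measured. Every SD given here is a spread across sites or genes. Libraries without the editor and nuclei without NeuN were not analysed here. The p-values compare sites or genes of one list and carry no replicate error.

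Gene names were matched to a RefSeq gene table of GRCm38.p6, the assembly that mm10 names. Of the 6929 gene names in the list, 6439 matched a symbol and 17 matched the synonym of one gene only, together 93.2% of names and 96.4% of sites. Of the matched sites, 98.5% (16861) lay inside the gene's span, and 0 genes had sites on both strands. The gene table gives spans and gene classes but no exons, UTRs, coding regions or strand. The strand of a site was therefore taken as the strand of its gene, and positions are given as distances to the 3′ or 5′ end of the span. Site positions are 1-based.

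The plan fixed before the data were examined held region shares (3′ UTR, coding sequence, intron), editing level contrasts between those regions, the base before the edited C, the 5-base m6A consensus, distance to the stop codon and the relation of editing level to coverage. These need a genome sequence, an exon annotation or coverage and were not run. In their place, chosen after the table had been seen, sites were counted in the last 5 kb and the first 1 kb of gene spans against uniform placement in the same spans (10000 draws). The planned results that were run are the number of sites and genes, the 2 comparisons of gene groups by Fisher's exact test, the editing level of synaptic genes against other genes, sites per gene against gene length, and the share of sites with another site within 100 nt. For that share the random sites were placed anywhere in the gene span (100 draws) and not on cytidines as planned.

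A set of 18 gene lists (markers of cortical cell types, synaptic and other functional groups, 436 different genes) was fixed before the data were examined. For each list the share of members with at least 1 site has an exact (Clopper-Pearson) 95% interval. Each share was also compared with 10000 random lists of protein-coding genes drawn from 20 bins of gene length; this comparison, and that of differences between 2 groups with the differences of their matched lists, were added later. The p-values of the lists are two-sided and were adjusted by the Benjamini-Hochberg method over the 18 lists. Without expression values, the share of a list with sites reflects both how much RNA of its genes was sequenced and how much of it was methylated. Editing levels were averaged per gene first, and gene means were compared with two-sided permutation tests of 100000 resamples, for which the smallest possible p is 1e-05. The gene-group comparisons form a family of 4 tests, adjusted together. Intervals of a difference of means come from 2000 bootstrap draws of genes.

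The genes named were chosen by a rule fixed before the data were examined: the 20 genes with the most sites, the 10 sites with the highest editing level (no coverage was at hand to filter them), up to 4 members of each list with the most sites (ties went to the higher mean level), every member with a site of the m6A machinery and nuclear long noncoding RNA lists, and Apobec1 and Ythdf2. Some genes and sites that this rule names are not reported here. The part of the rule on intronic and coding sites could not be applied. Alternatives were an editing minimum of 20%, a minimum of 2% (added later), 2 sites per gene in place of 1, sites in place of genes as units, medians in place of means and other windows. The tests were checked on simulated data. With gene means drawn from this list, the permutation test of 60 against 2000 genes called 4 of 100 null sets and 98 of 100 sets with a planted 1.5-fold difference. Fisher's exact test with 60 and 90 genes called 6 of 100 null sets and 82 of 100 sets with shares 0.25 apart. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.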

Results

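The nuclei of cortical cells sorted for NeuN were profiled for C-to-U conversion by APOBEC1-YTH, to locate m6A in nuclear RNA of neurons. One group of 2 libraries was analysed by the authors into a single list, so the comparisons below are between genes, gene groups and parts of genes within that list. The sequencing depth of the libraries is unknown from the table. The list held 17755 sites in 6929 genes, 8761 on the plus and 8994 on the minus strand.

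Most sites were edited at a low level. The median editing level was 3.64%, with quartiles of 2.01% and 6.90%. Levels of at least 10% were reached by 2642 sites (14.9%) and levels of at least 20% by 358 sites (2.02%). Of the genes, 3408 (49.2%) had a single site, 937 had at least 5 sites and 26 had at least 20 sites. The 937 genes with at least 5 sites held 42.4% of all sites. Protein-coding genes accounted for 16668 sites and long noncoding RNA genes for 401 sites in 229 genes. Of 21896 protein-coding genes in the RefSeq table, 6194 (28.3%) had at least 1 site. Chromosome 2 held the most sites (1658) and chromosome Y the fewest (3).

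The genes with the most sites included several that are known for their expression in astrocytes. Aqp4, the aquaporin of astrocyte endfeet (chromosome 18, 15389394 to 15410982), came first with 45 sites at a mean level of 3.73% ± 2.54 (SD across sites). Slc1a2, the main glial glutamate transporter (chromosome 2, 102658239 to 102790784), had 38 sites at 1.83% ± 1.66. Kcnj10, an inwardly rectifying potassium channel of glia (chromosome 1, 172341210 to 172374085), had 36 sites at 2.83% ± 3.01. Gja1, the gap junction protein connexin 43 (chromosome 10, 56377300 to 56390419), had 33 sites at 2.65% ± 1.70, and Slc1a3, the second glial glutamate transporter, had 23 sites at 1.80% ± 0.70. The transcriptional repressor gene Zbtb20 had 33 sites, Lrrc58 33, the cadherin-related gene Fat3 32, and the cytolinker gene Dst 29. Paqr8 and Arhgap5 had 28 sites each, the ankyrin gene Ank2 27, Ahnak 26 and Igfbp5 24. Fryl and Xist, the noncoding RNA of X inactivation, had 23 sites each. Astn1, a neuronal adhesion gene, Chst2 and the transcription factor gene Pou3f3 had 22 sites each.

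**Figure D1:**
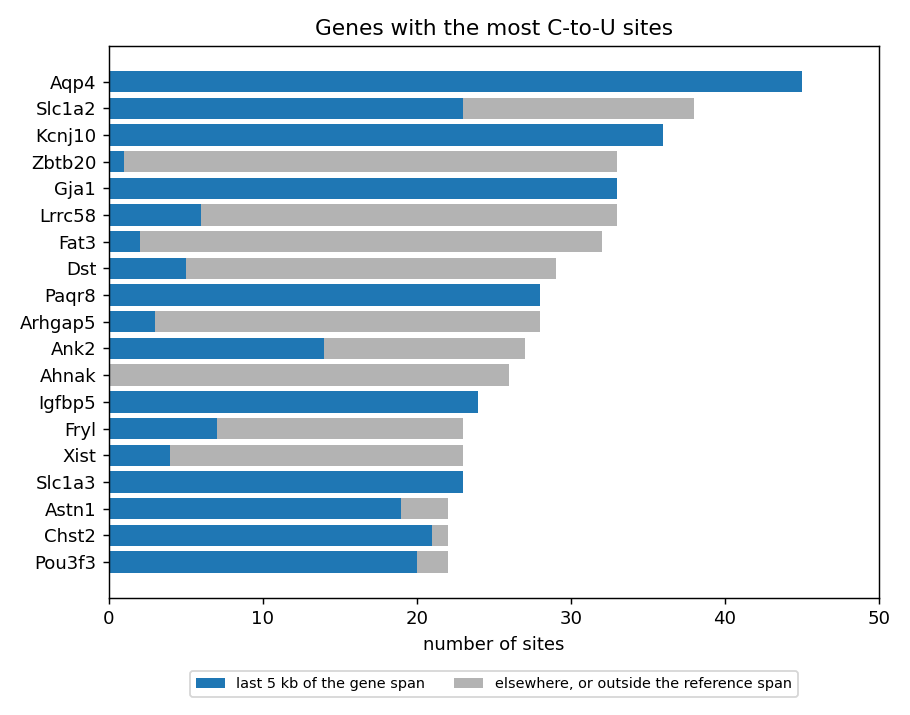
Number of C-to-U sites (horizontal axis) in genes with the most sites (vertical axis, those reported here), split into sites in the last 5 kb of the RefSeq gene span and all others. All 45 sites of Aqp4 lay in its last 5 kb, as against 0 of the 26 sites of Ahnak.

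Sites were concentrated towards the 3′ ends of genes. Of the 16861 sites inside a matched gene span, 8377 (49.7%, exact 95% interval 48.9% to 50.4%) lay within 5 kb of the 3′ end, where uniform placement would put 20.6%. None of 10000 random placements of the n = 16861 sites reached the observed share (highest 21.5%, p = 1e-04, one-sided, the smallest they can give). All 45 sites of Aqp4, all 36 of Kcnj10, all 33 of Gja1, all 28 of Paqr8, all 24 of Igfbp5 and all 23 of Slc1a3 were in that stretch. In other genes the sites lay far from the end. Ahnak had 0 of 26 sites in the last 5 kb, Fat3 had 2 of 32, Arhgap5 3 of 28, Dst 5 of 29 and Lrrc58 6 of 33. A second, smaller concentration lay at the 5′ end. In genes of 20 kb or more, 771 of 12750 sites (6.05%, exact 95% interval 5.64% to 6.47%) were in the first 1 kb, against 1.74% under uniform placement (p = 1e-04 from 10000 draws, one-sided). Whether a site was exonic or intronic was not determined, because the gene table gives spans only. The random placements used whole spans, introns included, and took no account of where reads lay. The excess at either end therefore does not separate methylation from read coverage.

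**Figure D2:**
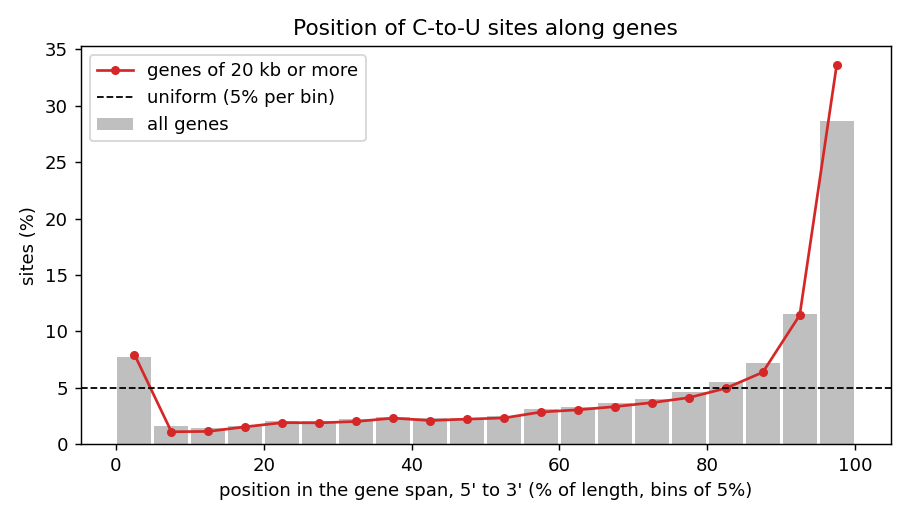
Share of sites (vertical axis, %) in 20 bins of the gene span from the 5′ to the 3′ end (horizontal axis, % of length), for all genes (bars) and for genes of 20 kb or more (line), with the uniform share of 5% per bin dashed. The last bin held 28.7% of the sites in all genes and 33.6% in genes of 20 kb or more, and the first bin held 7.70% and 7.95%.

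Listed editing levels were higher near the 3′ end than in the rest of the gene. Gene means were 6.96% ± 5.30 (SD, n = 4071 genes) in the last 5 kb and 5.26% ± 4.74 (SD, n = 3922 genes) elsewhere, a difference of 1.70 percentage points (bootstrap 95% interval 1.48 to 1.92, two-sided permutation p = 1e-05, the smallest possible). Among the 1618 genes with sites in both parts, 1147 had the higher mean near the end, and the mean difference was 1.96 points (two-sided sign-flip permutation p = 1e-05). The median level per site fell from 4.88% in the last 500 bp to 2.66% at more than 100000 bp from the end. Low levels can be called only where many reads cover a site, and coverage along the genes is not given. The difference therefore does not show stronger editing near the 3′ end. Among sites edited at 20% or more the difference of 0.25 points did not pass the test (bootstrap 95% interval -2.39 to 2.74, permutation p = 0.86). The median gene mean there was 20.0% in both parts, equal to the minimum itself. That contrast could hardly show a difference and decides nothing.

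Marker genes of glia and blood vessels carried sites more often than neuronal markers, although the nuclei had been sorted for NeuN. Of 60 neuronal markers, 26 had a site (43.3%, exact 95% interval 30.6% to 56.8%). Of 90 glial and vascular markers, 64 had a site (71.1%, 60.6% to 80.2%). The difference of -27.8 percentage points gave an odds ratio of 0.313 (95% interval 0.148 to 0.651, two-sided Fisher's exact test p = 0.0011, adjusted p = 0.0021 over 4 tests). With sites of at least 20% only, 2 of 60 and 4 of 90 markers had a site and the difference no longer passed Fisher's exact test (p = 1).

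The astrocyte list had 17 of 20 members with a site and 206 sites in all, with Aqp4, Slc1a2, Gja1 and Slc1a3 in front. The oligodendrocyte list had 18 of 20 members with a site, among them the myelin genes Mal (16 sites, mean level 1.87%), Mobp (9 sites, 1.82%) and the lineage genes Olig1 (7 sites, 3.67%) and Myrf (7 sites, 2.47%). The precursor list had 7 of 10, with 20 sites in Ptprz1, 4 in Cspg4 and 2 each in Pdgfra and Tmem100. The microglia list had 10 of 20, among them 6 sites each in Csf1r, Cx3cr1 and Selplg and 3 in P2ry13. The endothelial and pericyte list had 12 of 20, among them 19 sites in Rgs5, 11 in Pdgfrb, 10 in Flt1 and 7 in Cdh5. Among neuronal lists, 9 of 20 pan-neuronal markers had a site, among them 5 sites each in the microtubule-associated protein genes Mapt (3.84%) and Map2 (2.67%), and 4 in Celf4 (13.4%). Among excitatory markers 10 of 20 had a site, with 5 sites in Rorb, 4 each in Camk2a (7.89%) and Tle4 and 3 in Cux1. Among inhibitory markers 7 of 20 had a site, among them 2 each in Adarb2 (13.4%), Sst (10.1%) and Sox6. Among members picked out after their values were seen, Rbfox3, which encodes the protein used for the sort, had 0 sites. So did the neuronal markers Tubb3, Stmn2, Syp, Gad1, Gad2 and Slc32a1. The astrocyte markers Apoe, Gfap and Aldoc had 0 sites and were the only members of that list without one.

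The markers that carried sites differed in level in the opposite direction. Gene means were 7.19% ± 4.44 (SD, n = 26 genes) for neuronal markers and 4.02% ± 3.57 (SD, n = 64 genes) for glial and vascular markers. The difference was 3.17 points (bootstrap 95% interval 1.34 to 5.12, two-sided permutation p = 0.00068, adjusted p = 0.0021). The astrocyte list had the lowest mean of the 18 lists, 2.28% ± 0.96. A low level can be called only where many reads cover a site, so levels of gene groups sequenced to different depths are not on an equal footing.

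**Figure D3:**
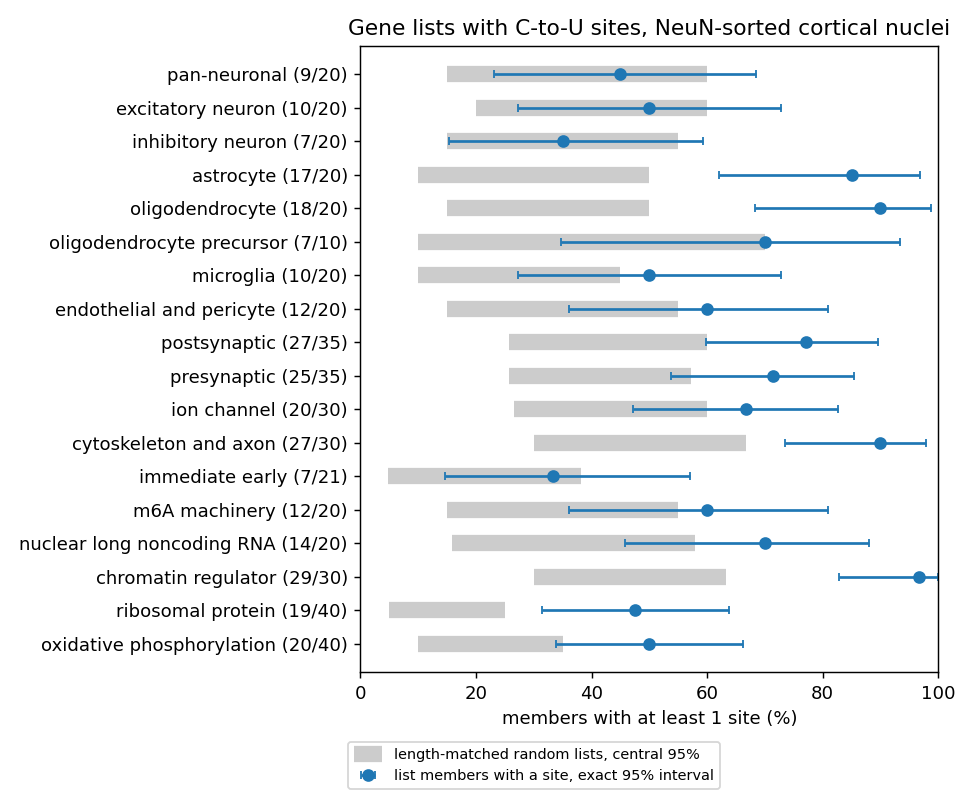
Share of list members with at least 1 site (horizontal axis, %) for the 18 gene lists (vertical axis, members with a site and members in parentheses). Points are observed shares with exact 95% intervals, and grey bars span the central 95% of 10000 length-matched random lists; the astrocyte (85.0%) and oligodendrocyte (90.0%) points lie to the right of their bars, and the 3 neuronal points lie within theirs.

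Synaptic genes carried sites more often than genes for ribosomal proteins and oxidative phosphorylation. Of 70 synaptic genes 52 had a site (74.3%, exact 95% interval 62.4% to 84.0%), against 39 of 80 (48.8%, 37.4% to 60.2%) in the other group. The odds ratio was 3.01 (95% interval 1.44 to 6.48, two-sided Fisher's exact test p = 0.0015, adjusted p = 0.0021). Genes of the same lengths gave a gap of like size: length-matched lists had a mean share of 42.5% for the synaptic and 17.7% for the other group. The observed difference of 25.5 percentage points exceeded the matched one of 24.8 points (central 95% of draws 10.7 to 38.8) by 0.75 points (n = 70 and 80 genes, p = 0.93, two-sided, from 10000 draws). The difference thus did not stand out from that of length-matched genes. Those genes were drawn whether or not cortex expresses them, so the comparison does not separate gene length from expression. On the postsynaptic side 27 of 35 genes had a site, among them the inhibitory scaffold gene Gphn (9 sites, 5.12%), Kalrn (8, 4.39%) and the AMPA receptor subunit gene Gria2 (8, 3.36%). On the presynaptic side 25 of 35 had a site, among them the active zone gene Pclo (14, 3.25%), Nrxn2 (7, 1.71%) and the vesicle priming gene Unc13a (5, 8.51%). In the ribosomal protein list 19 of 40 genes had a site and none had more than 2, with 2 each in Rpl15, Rps6, Rpl37 and Rps24. In the oxidative phosphorylation list 20 of 40 had a site, with 3 in Sdha and 2 each in Cox6c, Atp5d, Ndufv1, Atp5c1 and Atp5b.

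Synaptic genes with sites had a mean level of 8.12% ± 5.62 (SD, n = 52 genes), against 6.56% ± 5.27 (SD, n = 6877 genes) for all other genes. The difference of 1.56 points (bootstrap 95% interval 0.18 to 3.22) passed the permutation test (two-sided p = 0.035, adjusted p = 0.035). The call rested on 1 gene. Without that gene the difference was 1.04 points in the same direction (permutation p = 0.15), and the difference of medians over all 52 genes was 1.28 points (permutation p = 0.070).

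Against random protein-coding genes of like length, 11 of the 18 lists had more members with a site and 0 had fewer (adjusted p under the threshold of 0.05). The random genes were drawn whether or not cortex expresses them. A list of expressed genes can therefore pass without more methylation. The largest share of the 18 lists was that of the chromatin regulators, where 29 of 30 genes had a site, against a mean of 46.5% in matched lists (n = 30 genes, adjusted p = 0.00072). The histone methyltransferase genes Kmt2c (16 sites) and Ash1l (14), the acetyltransferase gene Crebbp (13) and the corepressor gene Ncor1 (12) led that list. Of the cytoskeleton and axon genes 27 of 30 had a site (n = 30 genes, matched mean 47.1%, adjusted p = 0.00072), among them Dst, Ank2, Map1b (18 sites, 7.02%) and Ncam1 (12 sites, 2.80%). Ion channel genes had 20 of 30 members with a site (n = 30 genes, matched mean 43.6%, adjusted p = 0.030), among them 4 sites in Scn8a (3.25%) and 3 each in Kcna2 and Kcnt1. Both ribosomal protein genes (47.5% against a matched mean of 14.3%) and oxidative phosphorylation genes (50.0% against 21.0%) were also above matched lists (n = 40 genes each, adjusted p = 0.00072 and 0.0010). The pan-neuronal, excitatory, inhibitory, precursor, microglia, immediate early and m6A machinery lists, each of n = 10 genes or more, did not pass (adjusted p = 0.60, 0.45, 1, 0.069, 0.050, 0.39 and 0.066). Immediate early genes had a site in 7 of 21 cases, led by Per1 (4), Junb (3), Dusp1 (3) and Jun (2). For the mean editing level, 0 of the 18 lists differed from the remaining genes after adjustment (permutation test, smallest adjusted p = 0.051), and 7 did at an unadjusted p under 0.05, 6 of them lower and 1 higher.

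Of the 20 genes for m6A writers, erasers and readers, 12 had a site. The writer complex genes Rbm15b and Zc3h13 had 6 sites each (mean levels 5.44% and 1.77%), Rbm15 5 and Wtap 2. Among reader genes, Ythdc1 had 5 sites, Ythdf3 4, Ythdf2 and Hnrnpa2b1 2 each and Ythdc2 1. Mettl16 and the demethylase genes Alkbh5 and Fto had 1 each. Apobec1, whose deaminase the transgene carries, had 0 sites. The 2 sites of Ythdf2 were at 1.85% and 15.8%. Among nuclear long noncoding RNAs, 14 of 20 genes had a site (n = 20 genes, 19 of them in the RefSeq table, adjusted p = 0.0024 against matched lists). After Xist came Kcnq1ot1 with 10 sites (9.76% ± 3.85), Meg3 with 9 (2.95% ± 2.25), Snhg14 with 8 (6.70% ± 6.19) and Peg13 with 6 (7.70% ± 1.96). Rmst, Snhg11, Neat1 and Malat1 had 4 sites each, C130071C03Rik 2, and Dlx6os1, Rian, Miat and Pantr1 1 each.

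The highest editing levels lay in different genes. Among the 10 highest were 94.9% in Actr1a (chromosome 19, position 46378003), 92.9% in Acvr1 (chromosome 2, 58567080), 91.1% in Cwc22 (chromosome 2, 77917102), 90.0% in Abcg4 (chromosome 9, 44288202), 85.7% in Scd3 (chromosome 19, 44235863), 83.3% in the pseudogene Gm18336 (chromosome X, 73398132), 62.8% in Gm10718 (chromosome 9, 3024448), 60% in Gm49249 (chromosome 15, 8529553) and 59.1% in Ints1 (chromosome 5, 139755230). The Acvr1 site lay outside the RefSeq span of its gene, and Gm10718 had no match in the RefSeq table. Reads of a pseudogene such as Gm18336 can be shared with its parent gene, so that level is uncertain. Only 14 of the 17755 sites reached 50% or more, against a median of 3.64%. Whether such values come from editing, a genomic variant read as C-to-T or misplaced reads was not tested.

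Longer genes had more sites. Across the 6454 genes with a site and a known span, the number of sites followed the log10 gene length with Spearman's rho = 0.281 and Pearson's r = 0.243 (permutation p = 1e-05 for each, the smallest possible; genes are not independent replicates). Among sites edited at 20% or more rho was 0.098 over 301 genes and did not pass the test (permutation p = 0.090). The share of protein-coding genes with a site went from 1.83% in the shortest of 10 length groups to 50.2% in the longest. Sites also lay close to each other. Of the sites inside gene spans, 23.3% (n = 16861 sites) had another site within 100 nt on the same strand, against 2.75% (range 2.32% to 3.05%) after 100 random placements in the same spans (p = 0.0099, one-sided, the smallest they can give). With placements that kept each site inside or outside the last 5 kb of its gene, the random share was 6.81%. Neither kind of placement took account of where reads lay, so clustering of methylation cannot be told from uneven coverage.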

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

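The minimum of 2%, the highest site per gene, the omission of 1 synaptic gene, the differences relative to length-matched lists, the random placement that kept the last 5 kb, and all tests of gene ends, gene starts and levels of neuronal against glial markers were chosen after the table had been seen. Of 35 recomputed values of the main results, 27 kept their direction and their side of the threshold (or, for counts, stayed within 1.5 times), 0 reversed, 7 no longer passed the test and 1 count moved further. That count was the number of sites, 358 (in 339 genes) at a minimum of 20%, against 13380 at 2%. At 20% the share difference between neuronal and glial or vascular markers was -1.11 percentage points (Fisher's exact test p = 1), the level difference of synaptic genes was 8.41 points over 6 genes (permutation p = 0.077), rho of sites per gene with gene length was 0.098 (permutation p = 0.090), and the level difference between the last 5 kb and the rest was 0.25 points (permutation p = 0.86). That minimum keeps 2.02% of the sites, so far fewer genes were tested. The median gene mean was 20.0% in the last 5 kb, in the rest and among non-synaptic genes. The level contrasts at 20% thus lay close to their own floor and decide little. The synaptic level difference was 1.28 points as a difference of medians (permutation p = 0.070; the cause was not tested) and 1.04 without 1 gene (permutation p = 0.15); over its 6 alternatives p ran from 0.00013 to 0.15. Relative to length-matched lists, the share difference between synaptic genes and those for ribosomal proteins and oxidative phosphorylation was 0.75 points (n = 70 and 80 genes, p = 0.93), and that between neuronal and glial or vascular markers was -33.4 points (n = 60 and 90 genes, p = 0.0002, the smallest the draws can give). The marker share difference was -19.4 points at 2% (Fisher's exact test p = 0.029), and the level difference between those markers was 2.57 points at 2% (permutation p = 0.018). For the 20 genes with the most sites, 34 of 40 recounts at the minimums moved by more than 1.5 times. Alternatives that needed coverage, an exon annotation or a spliced length were not run. No paired analysis was possible because the labels hold 1 group and the table combines both libraries, which also ruled out leaving out a library. The depth is unknown, the calling settings are not given and the list stops at 1.0%. A gene without a site may have been unmethylated, read too rarely, edited below that level or removed in calling. The list does not tell which.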

Other observations

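The predictions on gene length and on overlapping genes were written before their results were seen; the other tests below, the gene families, the comparison of long noncoding with protein-coding genes, the chromosome Y values and the genes named here were chosen after. Families that cortex is not expected to use had almost no sites. Of 1110 olfactory receptor genes 2 had a site (0.180%, exact 95% interval 0.022% to 0.649%), Olfr46 and Olfr461, and 0 of 355 vomeronasal receptor genes and 0 of 53 keratin genes had one. Among 12 families compared with length-matched genes, those 3 had a site less often (n = 53 genes or more, adjusted p = 0.0006 each). RNF ring finger genes (43 of 83, matched mean 31.4%, adjusted p = 0.0006), the zinc finger families Zbtb (22 of 41, 29.7%, adjusted p = 0.0053) and Zfp (145 of 397, 30.1%, adjusted p = 0.011), Rab genes (34 of 69, 33.2%, adjusted p = 0.014) and ubiquitin-specific proteases (30 of 56, 37.8%, adjusted p = 0.028) had one more often (n = 41 genes or more). Protocadherins (19 of 69), solute carriers (112 of 375), potassium channels (24 of 94) and glutamate receptors (10 of 27) did not pass the test. Expression was not matched here either, so the family shares do not separate expression from methylation.

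Long noncoding RNA genes had a higher mean level (8.20% ± 6.63, SD, n = 229 genes) than protein-coding genes (6.29% ± 4.94, n = 6195), a difference of 1.90 points (bootstrap 95% interval 1.05 to 2.80, two-sided permutation p = 1e-05, the smallest possible). Low levels can be called only where many reads cover a site, and the depth of either class is unknown. The difference therefore does not show stronger editing of long noncoding RNA. The list held 3 sites on chromosome Y, 2 in Kdm5d and 1 in Ddx3y, beside the 23 sites in Xist; the labels give no sex.

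The first pattern is that glial and vascular markers carried sites more often than neuronal markers in nuclei sorted for NeuN. Gene length is argued against, since the neuronal markers were longer (median 51581.5 bp, against 18547 bp for glial and vascular markers) and longer genes had sites more often. With log10 length in a logistic model over 150 genes the odds ratio for neuronal markers was 0.222 (95% interval 0.103 to 0.478), against 0.311 without it. Given those lengths, the model could hardly have moved the odds ratio the other way, so it adds little. A list wholly from nuclei without neurons is argued against, since 42.5% of excitatory and inhibitory markers (17 of 40, exact 95% interval 27.0% to 59.1%) had a site, against 0.132% (upper bound 0.475%) of the receptor and keratin genes; this test replaced one that decided nothing (43.3% of neuronal markers, length-matched range 25.0% to 48.3%), takes the markers to be silent outside neurons, and says nothing of the share of neurons. RNA of non-neuronal cells, bound to or sorted with the nuclei, may account for the pattern: 4 of the 5 glial and vascular lists lay above the central 95% of length-matched lists and the precursor list did not, and of abundant glial transcripts Mbp had 1 site, but Apoe, Gfap and Aldoc 0. It stays open, because the NeuN gate would remove such nuclei, the neuronal and non-neuronal lists share 0 genes but how many of the latter neurons also transcribe was not determined, and a difference in expression or methylation was not tested.

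The second pattern is a window of chromosome 6 (130 to 140 Mb) with 7 of its 34 sites at 30% or more, against 71 of 17755 in the whole list; they lie in Gm43984, Etv6, Lrp6 (2 sites), Fam234b (2 sites) and Eps8. Chance placement is argued against (p = 0.0002 from 10000 permutations of the levels over 271 windows). A strain variant that reads as C-to-T could give such values and stays open: the median of the other 27 sites was 5.56%, at the upper end of the range that as many sites drawn elsewhere gave (2.35% to 5.56%). The rule for that test first counted a median at the bound as going with a variant and was tightened after the value was seen, so it decides nothing. No biological explanation was tested.

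The third pattern is the concentration of sites in the first 1 kb of long genes, 771 sites in 656 genes. A strand given the wrong way round is argued against, because the starts do not mirror the ends: of the sites within 5 kb, 49.9% lay in the nearest 500 bp at starts and 12.3% at ends, 37.6 points apart (95% interval 34.5 to 40.6). Reads of a neighbour are argued against as the main source, with 10.6% of these sites (exact 95% interval 8.55% to 13.03%) inside the span of another gene and 8.62% of the other sites of the same genes. Methylation near gene starts and a higher coverage there stay open as untested.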
